A study of Mus musculus with 5 samples.

How the data were processed

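Nascent strands were prepared from CGR8 mouse embryonic stem cells grown with leukaemia inhibitory factor and without feeder cells, per the labels' protocols. DNA strands of the size of nascent strands were taken from a sucrose gradient, phosphorylated and digested with lambda exonuclease in 2 rounds, and made into Illumina libraries. The labels describe 3 nascent strand samples from independent cultures, 1 sonicated genomic DNA control and 1 RNase A control.

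The file analysed is the authors' deposited list of initiation zones, which combines the 3 nascent strand replicates, per the series' design text. It has 3 columns, chromosome, start and end in bp, and no score, read number or strand. The submitters' processing notes name CASAVA 1.8, SICER and build mm9. How these tools were set, and how the controls entered the calls, is not given in the sources used here. All 35512 zones start on a multiple of 200 bp and have a width that is a multiple of 200 bp when the end is counted as part of the zone. No zones overlap, and no 2 zones lie closer than 800 bp. The threshold on signal sets how many zones a region shows, and a region with less sequence coverage can lose zones. Because the list is pooled, no value could be computed per replicate. Because it holds no read counts, no depth, floor or interval for a zone could be given. Exact Poisson intervals on zone numbers cover counting error only.

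Positions are printed counting from 1, in mm9. The gene table used (RefSeq, GRCm38.p6, 49997 genes) is of another build: the last zone of chromosome 1 ends 1778161 bp past its last gene there. Apart from this check of the build, no coordinate of that table was used. Only the number of its genes named to each chromosome entered, with 8.67 ± 2.47 protein-coding genes per Mb of zone span over the autosomes. The planned comparisons of zones with gene starts, with 8 gene lists and with GC content need an annotation or sequence of mm9 and were not run, and for the same reason no gene is named.

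The span of a chromosome was taken from its first to its last zone. Zones were assigned to windows by their midpoint, and only windows wholly inside the span were kept. Random placement kept each chromosome's zone widths, the 200 bp grid and the shortest distance of 800 bp, and was repeated 1000 times over the chromosome or inside 1 Mb windows. The ranges given for single chromosomes rest on 200 placements, and the profile of distances on 100. Two-sided permutation p-values count placements as far from their mean as the observed value. Correlations of windows were computed on counts centred per chromosome. Correlations over chromosomes used 100000 permutations, or 20000 when each chromosome was left out in turn. Widths were shifted circularly along chromosomes 1000 times. The 7 planned tests were adjusted by Benjamini-Hochberg. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 was used.

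The tests were checked on simulated lists, 20 of each kind, with 100 placements each. Each list started from 35507 zones placed at random. Those with sparse blocks ended with fewer, because zones were removed to make the blocks. Among lists placed at random, a p under 0.05 came out in 1 list for clustering, in 0 for clustering inside 1 Mb windows and in 3 for regional variation. Lists in which 10% of the zones had been moved next to another were called by the 3 tests in 20 of 20. Lists with alternating dense and sparse blocks were called for regional variation in 20 of 20 and for clustering inside 1 Mb windows in 3. They were also called for clustering over the chromosome in 20 of 20. The tests of clustering over the chromosome and of regional variation therefore do not tell these kinds of list apart. The test of width against density gave a p under 0.05 in 14 of 20 random lists, with rho at most 0.02 below the shifted mean, since a wide zone leaves less room within 500 kb of its midpoint. Counting from the edges of the zone brought this to 1 of 20, and this was added as an alternative. Lists with zones made 400 bp wider in dense blocks were called in 20 of 20 by both. Of these lists, 6 of 20 were also called for clustering inside 1 Mb windows, although no zones had been moved together.

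The regions to be named were fixed before the data were examined: the 5 widest zones, the 5 longest stretches between zones, the 5 windows of 1 Mb with most zones, the chromosomes of highest and lowest density and chromosome X. Other chromosomes named were chosen after their values were seen, as were the 3 longest stretches on autosomes. Alternatives, also fixed then unless said otherwise, were neighbour distances of 5 and 20 kb, zones under 1 kb left out, zones under 1 kb apart joined, windows of 250 kb, 500 kb and 2 Mb, local densities within 250 kb and 1 Mb, covered length in place of zone number, all genes in place of protein-coding genes, autosomes only, and stretches over 500 kb left out of the space.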

Results

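Short nascent DNA strands were sequenced from CGR8 cells, a mouse embryonic stem cell line, to locate the places where DNA replication starts. Such strands begin at replication origins and carry an RNA primer, which protects them from lambda exonuclease, an enzyme that digests DNA from its 5′ end. The 5 samples comprised 3 nascent strand preparations from separate cultures, 1 control of sonicated genomic DNA treated with the exonuclease, and 1 control in which RNase A removed the primers first. The values reported here come from 1 list of initiation zones, which combines the 3 nascent strand replicates. The list gives a position for each zone and no read count, so the sequencing depth behind a zone is unknown. It has no value per replicate or per control, so the spread between cultures cannot be given, and the background in the 2 controls was not analysed here. Spreads below are over chromosomes, which are not biological replicates. All positions are in build mm9.

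How large initiation zones are, and how much of the genome they take up, was examined first. The list held 35512 zones, of which 35138 lay on the 19 autosomes, 369 on chromosome X and 5 on chromosome Y. The median zone was 2600 bp wide, with quartiles at 1400 and 4600 bp and a range from 200 bp to 81.0 kb. Median widths per autosome had an SD of 457 bp (n = 19 autosomes), from 1800 bp on chromosome 3 to 3400 bp on chromosome 11. Zones covered 139.9 Mb, or 5.44% of the 2574 Mb between the first and the last zone of each chromosome. Coverage per autosome was 5.85% ± 2.34 (SD, n = 19), lowest on chromosome 3 at 2.81% and highest on chromosome 11 at 11.9%. Zones of 10 kb or more made up 7.34% of the zones and 29.5% of the covered length.

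The widest zone spanned 81.0 kb on chromosome 11 from 118336001 to 118417000, and 23 other zones lay within 250 kb of it. The second, of 76.8 kb, lay on chromosome 11 from 3023401 to 3100200 and was the first zone of that chromosome. The third covered 61.2 kb of chromosome 17 from 27427001 to 27488200, inside one of the 5 densest windows described below, and had 39 other zones within 250 kb. The fourth covered 56.0 kb of chromosome 10 from 80745601 to 80801600. The fifth covered 55.2 kb of chromosome 1 from 90122201 to 90177400, with 5 other zones within 250 kb. Genes in these intervals are not named, because the gene annotation used here is of another build.

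The distribution of zones over megabase regions was compared with random placement. Zones were concentrated in a minority of the genome: the densest 10% of 1 Mb windows on autosomes held 29.3% of the autosomal zones, and the sparser 50% held 17.2%. Autosomal windows held a median of 11 zones, with the 10th and 90th percentiles at 2 and 33, and 64 of the 2385 windows had none. The window with most zones was on chromosome 2 from 30000001 to 31000000, with 69 zones. The next were on chromosome 4 from 140000001 to 141000000 with 68 zones, on chromosome 7 from 29000001 to 30000000 and on chromosome 17 from 27000001 to 28000000 with 67 zones each, and on chromosome 8 from 122000001 to 123000000 with 64 zones. The variance of the counts was 11.6 times their mean, against 2.12 for zones placed at random over each chromosome (95% range of 1000 placements 2.08 to 2.17). The two-sided permutation p was 0.001, the smallest that 1000 placements can give (0.0012 after Benjamini-Hochberg adjustment over the 7 planned tests). On the autosomes alone the ratio was 7.47 times that at random.

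Dense and sparse windows formed long stretches. Counts in adjacent 1 Mb windows of a chromosome correlated at r = 0.63, against a 95% range of -0.05 to 0.04 when windows were permuted within chromosomes (permutation p = 0.001, the smallest possible here, adjusted p = 0.0012). The correlation was 0.20 at 5 Mb, 0.11 at 10 Mb and 0.08 at 20 Mb, and lay above the permuted range at each of the 20 distances from 1 to 20 Mb. Windows are not independent replicates.

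**Figure D1:**
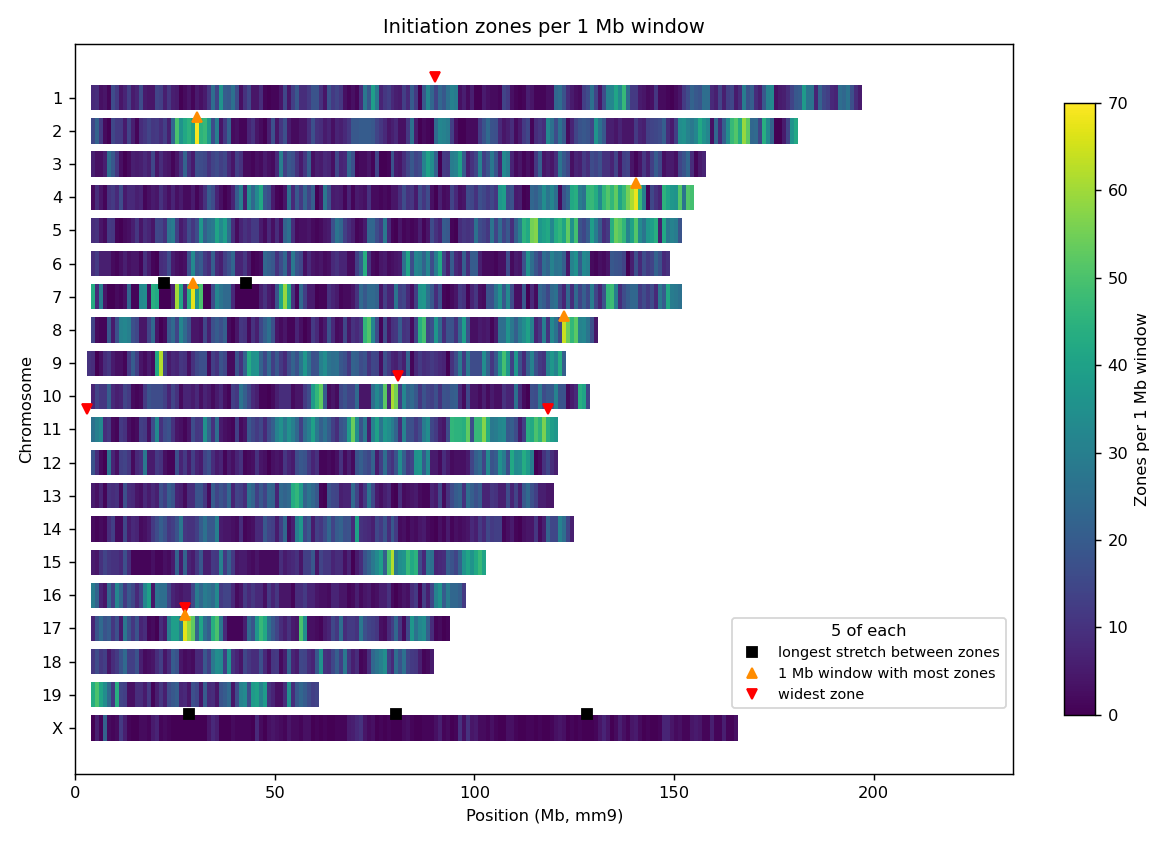
Number of initiation zones in each 1 Mb window (colour, 0 to 70 zones) along the autosomes and chromosome X, with position in Mb of mm9 on the horizontal axis and markers for the 5 widest zones, the 5 longest stretches between zones and the 5 windows with most zones. Chromosome 11 carried the most zones per Mb, dense windows lay in runs, and chromosome X had a median of 1 zone per window and at most 22, against a median of 11 on the autosomes.

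Stretches without a zone were as uneven. Neighbouring zones were separated by a median of 24600 bp, with quartiles at 7800 and 66200 bp. At the other extreme, 686 stretches of over 500 kb held no zone and together made up 24.8% of the span. The longest ran for 10.4 Mb on chromosome X from 23270601 to 33651000. The second was on chromosome 7 from 39302201 to 46404000 (7.10 Mb). The third and the fourth were on chromosome X, from 78317001 to 82378400 (4.06 Mb) and from 126285201 to 130220400 (3.94 Mb), and the fifth was on chromosome 7 from 20620001 to 24124400 (3.50 Mb). The 3 longest stretches on autosomes all lay on chromosome 7. Whether unmappable sequence or assembly gaps lie in these stretches could not be read from the list.

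Whether zones lie close to one another was tested on the distance to the nearest zone. Of all zones, 46.2% had another zone within 10 kb, against 26.0% for random placement over each chromosome (95% range 25.4% to 26.6%), a ratio of 1.77 (two-sided permutation p = 0.001, the smallest possible here, adjusted p = 0.0012). When each zone was instead placed at random inside its own 1 Mb window, which keeps the regional density, 39.95% had such a neighbour (95% range 39.4% to 40.5%), so the observed share was 1.16 times the random one (permutation p = 0.001, adjusted p = 0.0012). This second test also called 6 of 20 simulated lists that had wider zones in dense blocks and no added clustering. Those zones were only 400 bp wider, and density was even inside each window. In the list itself median widths ran from 1600 bp in the sparsest to 4800 bp in the densest regions. The rate of such calls for a list like this one is therefore unknown. The observed share lay above the 95% range of 200 placements inside 1 Mb windows on each of the 19 autosomes. On chromosome X it was 9.76% against a mean of 8.77% at random, inside the range of 5.15% to 12.5%. With only 369 zones this range is wide, so clustering on chromosome X is neither shown nor excluded. On chromosome 11 the share was 59.2% against 51.3% at random, and on chromosome 3 it was 32.8% against 28.0%.

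Inside 1 Mb windows the ratio to random placement was highest at the shortest distances. The shortest distance in the list, 800 bp, occurred between 1055 pairs of neighbours, against a mean of 116.5 at random, a ratio of 9.06. This ratio is too high, because the random draws gave 800 bp less often than each of the next 200 bp steps. Over the steps from 1 to 2 kb the random mean was 1134 pairs, against 2402 observed, a ratio of 2.12. At 2 to 5 kb the ratio was 1.02, and between 5 and 500 kb it lay from 0.89 to 0.97. It was again above 1 at 500 to 1000 kb, with 512 pairs against 440.3 (1.16), and at 1000 kb or more, with 176 against 148.5 (1.19).

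**Figure D2:**
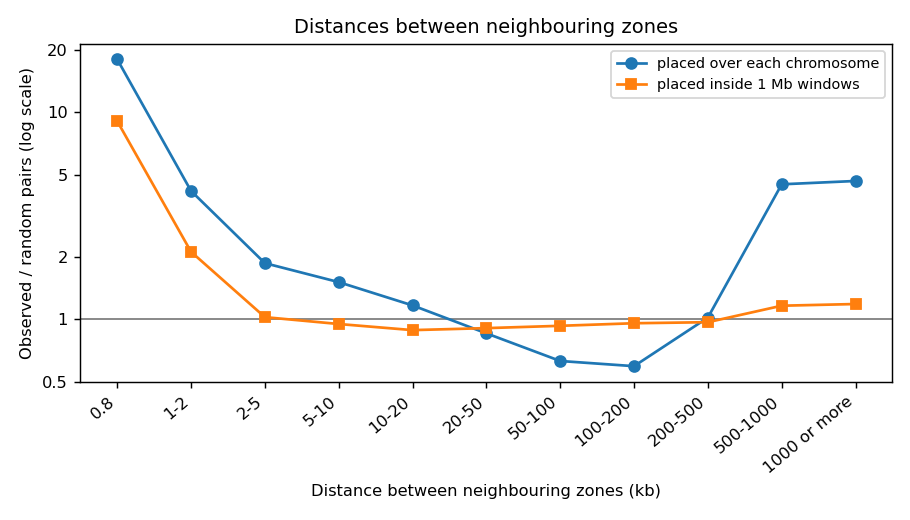
Number of pairs of neighbouring zones at each distance (horizontal axis, kb) divided by the mean number in 100 random placements (vertical axis, log scale), with zones placed over each chromosome (circles) or inside 1 Mb windows (squares). A value of 1 means as many pairs as at random. Inside 1 Mb windows the ratio was 9.06 at 0.8 kb and 1.02 at 2 to 5 kb. At 0.8 kb both ratios are too high, because the random draws gave this distance less often than each of the next 200 bp steps.

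Zone width was then compared with the number of zones nearby. Wide zones lay in zone-dense regions: zones with 36 to 81 others within 500 kb had a median width of 4800 bp (quartiles 2600 and 8400 bp), and zones with 0 to 13 others had a median of 1600 bp (quartiles 1000 and 2400 bp). Zones of 10 kb or more made up 18.96% of the former and 0.21% of the latter. Spearman's rho across zones was 0.51, against a mean of 0.07 when widths were shifted along their chromosomes (95% range 0.02 to 0.13, permutation p = 0.001, the smallest possible here, adjusted p = 0.0012). Zones are not independent replicates. Within single autosomes rho was 0.47 ± 0.05 (SD, n = 19) and above 0 on all 19, and on chromosome X it was 0.28.

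**Figure D3:**
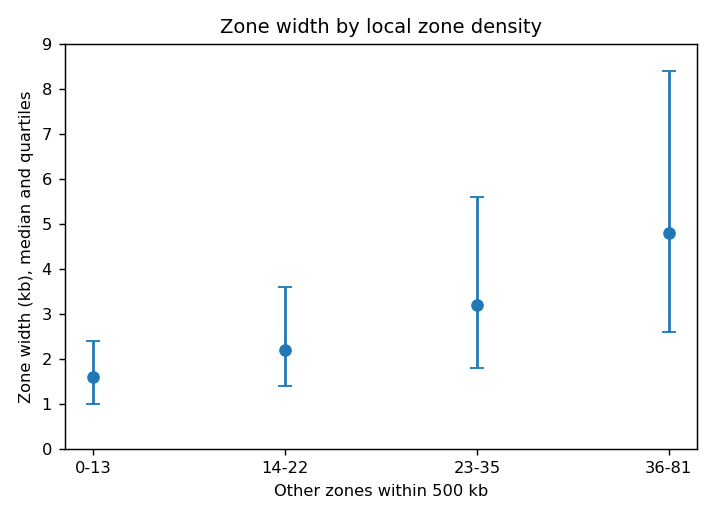
Zone width in kb (points, median; bars, lower to upper quartile) in 4 classes of local density, given as the number of other zones within 500 kb of the midpoint of a zone. The median was 1600 bp in the sparsest class, 2200 and 3200 bp in the middle classes and 4800 bp in the densest.

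Chromosomes were compared by zone density. Autosomes carried 14.7 ± 3.10 zones per Mb (SD, n = 19), from 10.2 on chromosome 14 to 22.4 on chromosome 11. Chromosome X carried 2.27 zones per Mb (95% exact Poisson interval 2.04 to 2.51, for counting error only), 6.47 times less than the autosomal mean and below every autosome. In an exact permutation over the 20 chromosomes the two-sided p was 0.05, which is the smallest this design allows. Zones on chromosome X were also narrower than on the autosomes as a whole, with a median of 1600 bp, and covered 0.46% of its span. They were not narrower than autosomal zones drawn to have as few zones around them, whose median was 1200 to 1400 bp. That comparison was chosen after related results were seen. Stretches of over 500 kb without a zone took up 75.3% of chromosome X, against 20.9% ± 4.97 of an autosome (SD, n = 19). When these stretches were left out of the span, chromosome X carried 9.15 zones per Mb and the autosomes 18.5 ± 3.40, so the ratio of X to the autosomal mean moved from 0.15 to 0.49. Fewer zones leave more such stretches even at random, so this move does not measure what the stretches contribute. The densest window of chromosome X, from 7000001 to 8000000, held 22 zones. The 5 zones of chromosome Y were too few to compare.

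Zone density was then set against the gene density of each chromosome. Chromosomes with more protein-coding genes per Mb carried more zones: chromosome 11 had 13.6 genes and 22.4 zones per Mb, chromosome 19 had 12.1 genes and 17.4 zones, and chromosome 3 had 6.34 genes and 10.8 zones. Over the 20 chromosomes Pearson's r was 0.75 (permutation p = 3e-05, adjusted p = 0.00021 over the 7 planned tests) and Spearman's rho 0.85 (permutation p = 3e-05). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.72 (permutation p = 0.00071). Chromosome X stood apart from the other chromosomes, and on the 19 autosomes alone r was 0.82 (permutation p = 2e-05) and rho 0.84. Chromosome 7, with the highest gene density at 13.6 genes per Mb, carried 16.2 zones per Mb and lay at -3.54 from the autosomal line. Chromosome 5, with 18.1 zones per Mb, lay at 3.58 above it. With stretches of over 500 kb left out of the span, Pearson's r over 20 chromosomes was 0.082 (permutation p = 0.73) and Spearman's rho 0.57 (permutation p = 0.0094). Without chromosomes X and 7, r was 0.81 (permutation p = 5e-05), so the low r rested on these chromosomes.

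**Figure D4:**
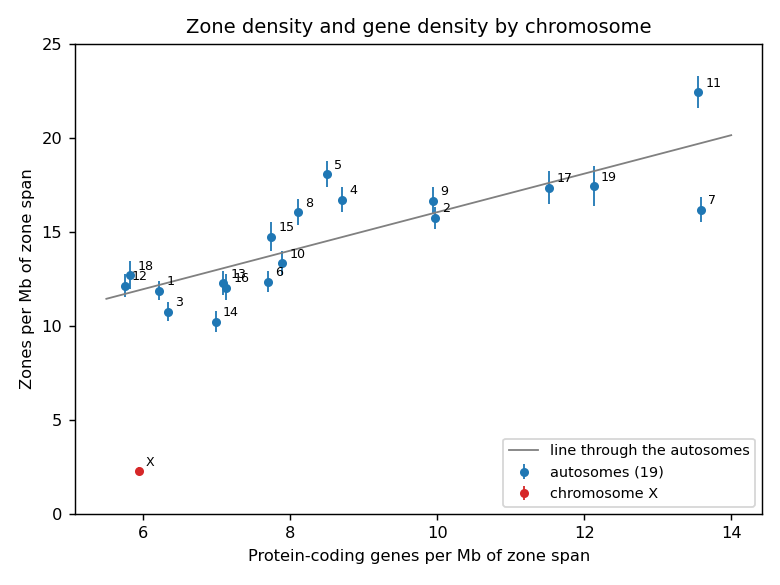
Zones per Mb (vertical axis, with 95% exact Poisson intervals) against protein-coding genes per Mb (horizontal axis) for the 19 autosomes and chromosome X, with the least-squares line through the autosomes. Chromosome X, at 5.94 genes and 2.27 zones per Mb, lay below the line and below every autosome.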

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

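No alternative reversed a result, and 60 of the 62 alternatives kept the direction and the side of the threshold, or moved a value without a test by less than 1 SD over the autosomes. This number includes leaving out each of the 20 chromosomes in turn for 1 result, and these runs overlap strongly. For the density of chromosome X no setting could give a p under 0.05, so the side of the threshold could not change. With stretches of over 500 kb left out of the space, the ratio of chromosome X to the autosomes moved from 0.15 to 0.49, and Pearson's r of zone density with gene density over 20 chromosomes fell to 0.082 (permutation p = 0.73), while the rank correlation was 0.57 (permutation p = 0.0094). The second change follows from construction, since 75.3% of chromosome X leaves the space while its genes all stay. Part of the first change does too, since fewer zones leave more stretches over 500 kb even at random. Leaving out each chromosome in turn gave r from 0.67 (without chromosome 11) to 0.82 (without chromosome X). Measured by covered length, chromosome X stood at 0.078 of the autosomal mean with an exact permutation p of 0.10, because chromosome 11 lay farther from the others. The share of zones with a neighbour within 10 kb stayed above random placement inside windows of 500 kb (46.2% against 41.6%) and 250 kb (46.2% against 42.8%). Counting neighbours from the edges of the zone, joining at 2 and 5 kb, autosomes only for the clustering tests, and the comparison of the chromosome ends at every length were chosen after seeing the data. No paired analysis was possible because the list pools the replicates, and leaving out each replicate was not run for that reason. Comparisons with gene starts, gene lists and GC content were not run. Depth is unknown, so weak zones missed by the caller cannot be bounded.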

Other observations

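Zones were more frequent toward the end of the autosomes with the highest coordinates, which in the acrocentric mouse chromosomes is the end away from the centromere. This comparison was not among the planned ones and was chosen after seeing the data, which its permutation p-values do not take into account. The last 10 Mb of the zone span held 21.4 ± 9.28 zones per Mb (SD, n = 19 autosomes), the first 10 Mb held 11.4 ± 6.03, and the part between held 14.2 ± 2.97. The last 10 Mb exceeded the first by 10.1 zones per Mb (sign-flip permutation p = 0.00087, adjusted p = 0.0013 over 3 contrasts), in 16 of 19 autosomes. Chromosomes 17, 18 and 19 went the other way, with 30.1 zones per Mb in the first 10 Mb of chromosome 19 and 16.4 in its last. The largest values in the last 10 Mb were 38.7 zones per Mb on chromosome 11 and 37.5 on chromosome 4. The last 10 Mb also exceeded the middle, by 7.21 (p = 0.00071 by permutation, adjusted p = 0.0013), in 15 of 19 autosomes. The first 10 Mb differed from the middle by -2.87 (permutation p = 0.061) and lay above it in 2 of 19 autosomes, chromosomes 16 and 19. With ends of 5 and 20 Mb the difference between the ends was 9.22 and 10.4. The gene content of the ends was not analysed here.

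Of the tests below, those on zones joined under 2 kb, on widths matched for density and on shuffled gene numbers were chosen only after related results were seen.

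The first pattern is the low zone density of chromosome X. Gene content alone is argued against: at 5.94 genes per Mb the autosomal line gives 11.9 zones per Mb (95% prediction interval 7.78 to 16.0), and chromosome X had 2.27. Long stretches such as unmapped sequence do not account for all of it either, since with every stretch over 500 kb left out chromosome X had 9.15 zones per Mb against 13.6 on the lowest autosome. A single copy of X, in a line known as male, stays open. The ratio to the autosomes was 0.15 (0.14 to 0.17, exact Poisson, for counting error only), below the 0.5 that calls in proportion to copies would give. However, a caller with a threshold need not lose zones in proportion, and a biological difference of the X was not tested. Density on X was 0.27 of the autosomal mean for zones under 2 kb and 0.0056 (0.00014 to 0.031, exact Poisson, 1 zone) for zones of 10 kb or more; yet 3.79% of X zones reached 5 kb, inside the 1.08% to 4.07% of autosomal draws with as few zones around them, and their median of 1600 bp lay above the 1200 to 1400 bp of those draws.

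The second pattern is the close spacing of zones. Of all zones, 46.2% had a neighbour within 10 kb, against at most 40.5% in 95% of placements inside 1 Mb windows. The same test also called 6 of 20 simulated lists with wider zones in dense blocks and no added clustering. Its rate of such calls for this list is unknown, so whether density differences between 1 Mb windows account for all of the close spacing stays open. Splitting of a single zone by the caller into pieces under 2 kb apart was tested by joining such pairs. The share was then 37.2%, above the 34.3% to 35.5% of placements of the joined zones inside 250 kb windows. With all zones placed inside 1 Mb windows, however, the excess of close pairs lay under 2 kb. The ratio to random was 1.02 at 2 to 5 kb and 0.95 at 5 to 10 kb. Density differences inside the 250 kb windows were also not taken out, so splitting into pieces under 2 kb apart stays open. Splitting over longer distances stays open: of 24892 domains made by joining within 10 kb, 74.2% had another within 50 kb, above placement in 1 Mb windows (71.7% to 72.7%) but not in 250 kb windows (73.3% to 74.2%, permutation p = 0.058). The prediction written beforehand used 1 Mb windows only, which leave density differences inside them, so it could not decide. The largest such domain held 26 zones, and 19119 domains held 1.

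The third pattern is the relation of zone density to gene density on the autosomes. The hypothesis was that olfactory, vomeronasal and trace amine receptor genes, large families of sensory receptors, follow the zones less than other genes, and leaving out the 1471 such genes raised Pearson's r from 0.82 to 0.89, a rise of 0.078. Removing as many random genes cannot judge this, since the families are spread unevenly, from 0 genes on chromosome 12 to 417 on chromosome 7. The numbers removed were therefore shuffled over the autosomes, and 11 of 10000 shuffles gave as large a rise (95% range -0.16 to 0.04). Without chromosome 7, which lay at -3.54 from the line, the rise was 0.040, reached by 78 of 10000 shuffles (95% range -0.08 to 0.03). Single chromosomes did not all follow: chromosome 2, with 287 such genes, lay at -0.27 from the line, chromosome 9, with 130, at 0.66, and chromosome 14, with 41, at -2.74. Few zones in these gene clusters may contribute, but shuffling also unlinks the families from chromosomes rich in other genes, and the positions of the genes were not tested.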
